A study of Mus musculus with 9 samples.

How the data were processed

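Single cells dissociated from the amygdala of C57BL/6J male mice aged 8 to 10 weeks were measured by droplet RNA sequencing with unique molecular identifiers (UMIs). Each of the 9 libraries pooled 4 to 5 mice. Per the labels' protocols, tissue was digested with papain at 20 units per ml and 30 °C for 45 minutes. This was done in the same period of the day for all libraries. Cells were measured only after this digestion, so its part in the level of any gene was not tested. The labels describe 3 experimental batches, each with 1 naive, 1 morphine-dependent and 1 withdrawal library. They do not state which replicate number belonged to which batch. Dependent mice had received morphine for 8 days, and withdrawal mice were collected 24 hours after it was stopped.

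The authors deposited matrices of whole-number UMI counts per gene and cell barcode, without normalization. The submitters' processing notes name Cell Ranger 6.1 and the mm10 genome build. The file headers carry version 6.0.1 for the replicate 1 library of each group and 6.1.1 for the other 6 libraries, so the software version changed with the replicate number and not with the group. The matrix of withdrawal replicate 3 held 15000 barcodes, with a lowest UMI count of 2155 per barcode, against 500 to 601 in the other 8 libraries. How its barcodes were selected was not given in the sources used here. Of the 32285 gene identifiers, 32158 were matched to the GENCODE M21 annotation (mm10), which supplied the coordinates. The annotation used for counting was not given in the sources used here.

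Cells with at least 500 detected genes and at most 15% mitochondrial counts were kept, which left 80913 cells. Scrublet was run per library with an expected rate of 0.8% per 1000 barcodes and marked 2717 of them as doublets, which were removed after clustering. Clustering used scanpy 1.11.5 with 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1, with no integration of libraries. It gave 56 clusters, of which 27 could be named as 18 classes from marker lists; these held 59124 cells. A class is called by its marker genes and the suffix "-like". A cluster stayed unnamed when under 50% or fewer than 3 of its markers were raised by a fold of 2, or when over 30% of its cells were predicted doublets. It also stayed unnamed when its median UMI count was below 33.3% of that of its libraries with under 70% of its markers raised. The same held when at least 70% of the markers of another lineage, or of both pericytes and smooth muscle, were raised, or when another neuron class had as many raised. It also held when none of its markers was among its leading 10 genes or another class had more there. These thresholds were set after the clusters had been seen.

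Counts were summed per library and class. A class was tested when each library had at least 30 cells of it, which 10 classes met. The main test was the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) with TMM factors and filterByExpr. It fitted all 9 libraries of a class together with group as the term, with Benjamini-Hochberg adjustment within the class and a threshold of 0.05. Fold changes are given as log2 with the standard error (SE), and levels as TMM-scaled CPM (counts scaled to a common library size) with the SD over 3 libraries. The 3 contrasts and a joint test of any difference were computed. Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, for lists with at least 5 tested genes. The adjustment ran over all lists and classes of a comparison. Alternatives were camera with an estimated correlation and fry. Of 28 gene lists, 24 had at least 1 call in some class and comparison. The cell-type marker lists were also tested in every class other than their own and were adjusted apart. Shares of cells used logit values with an offset of 0.5 cells and an exact permutation test of the F statistic over the 3 groups. Pairwise tests of 3 against 3 libraries cannot give a p below 0.1.

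Test, samples, gene lists, marker lists, the first set of alternatives and the rule for named genes were fixed before the data were examined. The rule took called pairs whose groups did not overlap, at most 8 in each direction and 3 per class and direction. It also took up to 3 members of smallest adjusted p of each called list, and always 9 genes of opioid and stress signalling in the class of highest level. Genes called in the same direction in the most classes were to be added, and none was called in more than 1 class within a comparison. It was read as naming, for a list called in a comparison, members in the classes where that list was called. Genes reported only from DESeq2 1.42.0, from the block or across classes were chosen after their values were seen. In the 3 comparisons the rule named 50, 70 and 60 genes; the text gives examples, and the others enter the counts of their lists. A result that the rule named is not reported here. The first alternatives were the replicate number as a block, DESeq2 size factors, the DESeq2 test, no filter on low counts, a fold limit of 1.2 and adjustment over all classes. Further ones were a stricter cell filter (1000 genes, 10% mitochondrial counts), doublets kept, removal of genes whose level in a class was under 5% of that in another, Leiden resolution 0.5, and leaving out each library. Shares were also tested within replicate numbers and without microglia-like cells. A common UMI floor of 2155, removal of clusters of low UMI count, and the floor together with the block were added after the data had been seen.

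The labels number the replicates alike in each group. Deviations of log2 CPM from the group means were correlated between same-numbered libraries over all classes together. For dependent and naive libraries the correlations were 0.30, 0.21 and 0.30 for numbers 1 to 3, each above the limit of 0.1 set for pairing, and each library correlated best with its own number. By this limit the numbers were taken to pair these libraries, and this pairing comes from the data and not from the labels. How often such a match arises by chance was not tested. The main test did not use the number. Counts of calls with the number as a block are given beside each comparison.

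The edgeR and camera steps were tested on counts simulated from the real means and library sizes with known fold changes, for dependent against naive libraries. At a 2-fold change the test recovered 61.2% of changed genes in microglia-like cells (13858 genes tested), 43.3% in oligodendrocyte-like cells (11451 genes) and 56.7% in pericyte-like cells (7882 genes). At a 1.5-fold change it recovered 26.9%, 11.9% and 8.96%. Unchanged genes made up 7.32%, 6.45% and 8.04% of the calls. For withdrawal against naive libraries with no gene changed, 0, 0 and 2 genes were called in microglia-like, oligodendrocyte-like and pericyte-like cells. Camera called the raised list in each of the 3 classes, also with an estimated correlation, and 2 unchanged lists in oligodendrocyte-like cells with the preset one. The simulated genes were drawn independently of each other. The simulation therefore does not show what camera recovers with an estimated correlation in lists whose genes vary together. Replicates are pools of different mice, so p-values measure the spread between pools. The depth of a class limits the smallest change that could be detected in it. Committed precursor, smooth muscle, ependymal, fibroblast, glutamatergic neuron, immature neuron, neutrophil and T or NK cell classes had too few cells for gene tests.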

Results

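Droplet libraries of amygdala cells were compared (9 in all), 3 from naive mice, 3 from mice dependent on morphine, an opioid agonist, and 3 from mice 24 hours into withdrawal. Libraries held 64826327 to 94875093 UMIs in 10407 to 15580 barcodes. After filtering, 4759 to 11967 cells per library remained, with median UMI counts of 4371 to 8497. Over the 3 groups, none of 11 library quality measures passed an exact permutation test (lowest adjusted p = 0.558). Withdrawal replicate 1 had the lowest share of barcodes kept (45.7%, against 59.1% to 77.4% in the other libraries). It also had the lowest median of genes per barcode (959, against 1300 to 2272) and the highest haemoglobin share (4.87%). Its kept cells had the highest median UMI count, 8497. The median mitochondrial share per barcode was 8.23% ± 0.26 in naive, 8.50% ± 0.9998 in dependent and 10.5% ± 1.23 in withdrawal libraries (SD, n = 3 each; exact permutation p = 0.0679).

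The first question was which cells were present and whether their shares differed between treatments. Astrocyte-like cells (Slc1a3, Gja1, Ntsr2) made up 35.4% ± 7.90 of named cells in naive, 38.4% ± 10.0 in dependent and 33.6% ± 11.1 in withdrawal libraries (SD, n = 3). Microglia-like cells (P2ry12, Cx3cr1) made up 18.7% ± 3.32, 19.7% ± 6.38 and 20.3% ± 4.42. In naive libraries oligodendrocyte precursor-like cells (Pdgfra, Cspg4) held 15.1% ± 2.27, endothelial-like cells (Flt1, Cldn5) 8.69% ± 1.61, oligodendrocyte-like cells (Mog) 4.68% ± 1.501 and GABAergic neuron-like cells (Gad1, Gad2) 1.77% ± 1.203. Committed oligodendrocyte precursor-like cells (Enpp6, Bmp4) were at 1.38% ± 0.211, 1.15% ± 0.203 and 0.751% ± 0.284 in the 3 groups. None of 18 classes passed the exact permutation test over the 3 groups. The committed precursor class had the lowest p, 0.05 unadjusted and 0.9 adjusted by the exact permutation test. The higher lowest UMI count of withdrawal replicate 3 and the dissociation of the tissue can also set these shares. A cluster of low UMI count led by Sst, Npy and Vip, with 50% of the GABAergic neuron markers raised and Gad2 among its leading genes, stayed unnamed and held 10.2% ± 6.35, 6.89% ± 5.57 and 4.74% ± 7.27 of the cells of the 3 groups. By replicate number it held 2.91%, 14.1% and 13.7% in naive, 1.63%, 6.31% and 12.7% in dependent, and 0.841%, 13.1% and 0.257% in withdrawal libraries. Its median UMI count was 793, below the lowest count of withdrawal replicate 3, 2155. Cluster 31, left unnamed for markers of both pericytes and smooth muscle, held 0.652%, 0.544% and 0.494%. The largest clusters left unnamed for markers of several lineages and for predicted doublets, numbers 23 and 21, held 1.003% and 1.21% of the cells in naive, 1.01% and 1.17% in dependent, and 1.06% and 0.951% in withdrawal libraries.

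**Figure D1:**
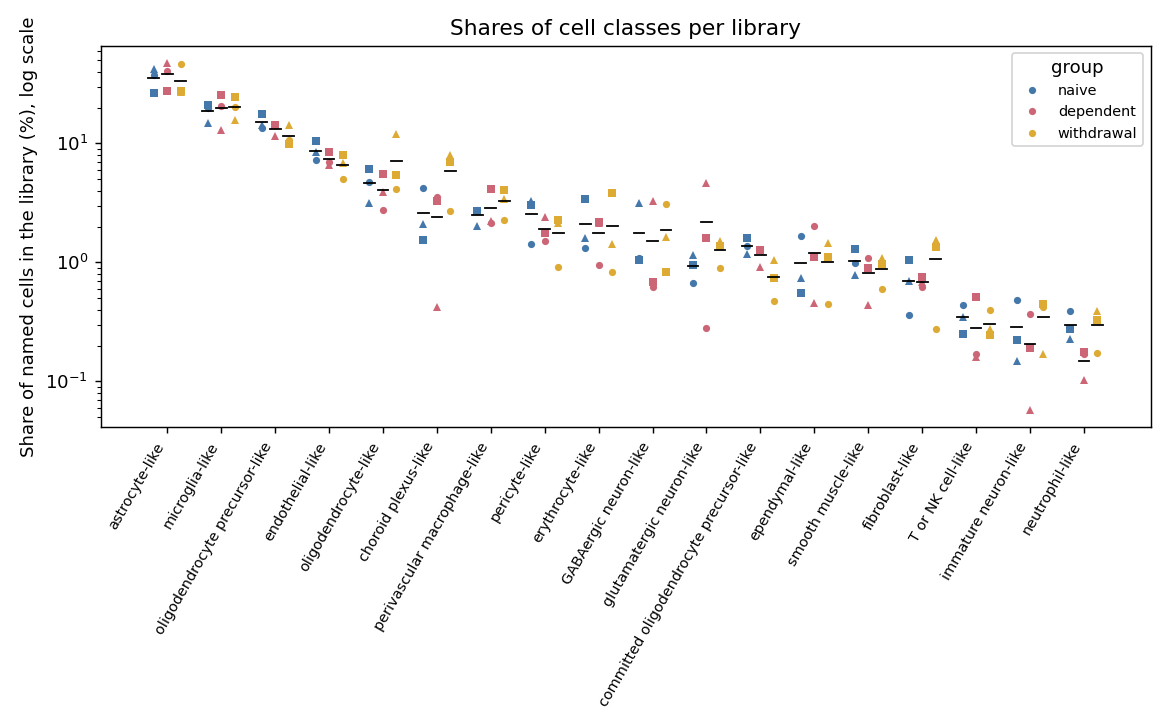
Share of named cells (%, log scale) in each of 18 classes. Points are libraries, coloured by group and shaped by replicate number (circle 1, square 2, triangle 3), and bars are group means; no class passed the permutation test.

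Dependent and naive libraries were compared to ask what 8 days of morphine changed in each class. In oligodendrocyte-like cells Hist1h1c, which encodes a linker histone, fell from 148 ± 13.1 to 55.0 ± 5.16 CPM (SD, n = 3). Its log2 fold change was -1.43 ± 0.12 (SE; edgeR adjusted p = 0.00078), with 3 of 3 dependent libraries below every naive library. In the same cells Hspa1a, an inducible HSP70 chaperone, rose from 80.7 ± 3.16 to 209 ± 21.3 CPM. Its log2 fold change was 1.37 ± 0.16 (SE; edgeR adjusted p = 0.00929), with 3 of 3 dependent libraries above every naive library. Hspa1a has a near-identical copy, Hspa1b, so its count is uncertain. The part of the tissue digestion in the Hspa1a level was not tested. Hist1h1c (ENSMUSG00000036181) lies on chromosome 13 at 23738808 to 23740367, and Hspa1a (ENSMUSG00000091971) on chromosome 17 at 34969190 to 34972156 (mm10). Some genes chosen after their values were seen had the same sign across classes. Hist1h1c had a negative fold change in 10 of 10 classes, with the groups apart in 7. Calr, a chaperone of the endoplasmic reticulum, had a negative one in 10 of 10 (apart in 9), and Dnajb1, an HSP40 co-chaperone, a positive one in 9 of 9 (apart in 4). The classes come from the same libraries, so these counts give no measure of chance.

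Several gene lists moved as groups by camera with the preset correlation. With an estimated correlation 0 of these calls remained, with an adjusted p = 0.934 for cell cycle genes in oligodendrocyte precursor-like cells and an adjusted p = 0.9996 for each other call with an estimated correlation. All cells were measured after papain digestion, and its part in the list changes of any comparison was not tested. Immediate early genes, which respond fast to stimulation, rose in 5 classes, of which 1 call was left without dependent replicate 2. In perivascular macrophage-like cells 24 of 24 members had positive values (median log2 fold change 0.23), and in endothelial-like cells 23 of 24 (median 0.30). Cytokine and NF-kB target genes rose in endothelial-like cells (median 0.70, 14 of 15 positive). There Icam1, a leukocyte adhesion molecule, was at 77.8 CPM in naive and 160 CPM in dependent libraries (log2 1.03 ± 0.19, edgeR adjusted p = 0.176, DESeq2 adjusted p = 0.000138), with 3 of 3 dependent libraries above every naive one. The same list rose in microglia-like cells (median 0.19). Heat shock and chaperone genes rose in microglia-like, oligodendrocyte-like and perivascular macrophage-like cells (medians 0.10, 0.14 and 0.28). They fell in astrocyte-like cells (median -0.15, 14 of 16 negative), where unfolded protein response genes also fell (median -0.16). Of the astrocyte-like cells, cluster 0 held 55.2% in naive and 48.2% in dependent libraries, and cluster 1, of lower UMI count, 43.8% and 50.8%. Cluster shares within a class, here and below, pool the cells of the 3 libraries of a group. By library cluster 1 held 38.4% to 50.5% in naive and 43.1% to 58.3% in dependent libraries. Circadian clock genes rose in 4 classes, with the highest median in pericyte-like cells (0.41), and 0 of these calls were left without dependent replicate 2 (pericyte-like median 0.15). Without naive replicate 1 the clock median in oligodendrocyte-like cells was 0.024, and the endothelial-like call held in 2 of 9 fits that left out 1 library. In oligodendrocyte precursor-like cells cell cycle genes fell (median -0.36), with Mcm3, a replication licensing gene, at 21.003 and 11.6 CPM, and interferon-stimulated genes fell (median -0.19). In that class cluster 9, of lower UMI count, held 27.8% of the naive and 18.3% of the dependent cells (by library 13.4% to 40.6% and 9.53% to 30.1%). Ribosomal protein genes rose in 4 classes and nuclear oxidative phosphorylation genes in GABAergic neuron-like and oligodendrocyte precursor-like cells (medians 0.29 and 0.11). Cholesterol biosynthesis genes fell in astrocyte-like and perivascular macrophage-like cells (medians -0.08 and -0.24). Mitochondrially encoded genes rose in choroid plexus-like and endothelial-like cells and fell in GABAergic neuron-like cells. Of these 2 rises 0 were left without dependent replicate 1 or naive replicate 1. The fall was kept only without naive replicate 2 or naive replicate 3. Blood-brain barrier genes rose in endothelial-like cells (median 0.11), where Slc7a1, a cationic amino acid transporter, had a log2 fold change of 0.67 ± 0.12 (edgeR adjusted p = 0.176), higher in 3 of 3 dependent libraries. Astrocyte uptake genes fell in GABAergic neuron-like and oligodendrocyte-like cells (medians -0.54 and -0.40), where astrocyte markers had medians of -0.64 and -0.46. Blood-brain barrier genes fell in GABAergic neuron-like cells (median -0.53). Homeostatic microglia genes fell in erythrocyte-like cells (median -0.66), where microglia markers had a median of -0.50. Glutamate receptor genes fell in perivascular macrophage-like cells (median -0.53). In all, 35 of 250 list and class pairs were called, 23 up and 12 down, and fry called 0 (lowest adjusted p = 0.311). Of the 35 calls, 6 held in each of the 9 fits that left out 1 library, 28 had a median that moved by over 1.5 times and 7 one of the opposite sign in at least 1 of them. Leaving out naive replicates 1 to 3 ended 15, 10 and 3 calls, dependent replicates 8, 13 and 12, and withdrawal replicates, which share the fit, 2, 2 and 3. Without dependent replicate 3, 0 of the ribosomal and oxidative phosphorylation calls were left, and without naive replicate 1, 0 of the 3 heat shock rises. Without dependent replicate 1 or naive replicate 2 the heat shock and unfolded protein response falls in astrocyte-like cells and the homeostatic microglia call ended, without dependent replicate 1 the glutamate receptor call, and without dependent replicate 2 the blood-brain barrier rise. Microglia-like cells lay in cluster 2 for 80.7% in naive and 87.1% in dependent libraries, and endothelial-like cells in cluster 24, of lower UMI count, for 16.8% and 13.6%. By library cluster 24 held 14.9% to 18.1% of endothelial-like cells in naive and 10.04% to 16.8% in dependent libraries. Without dependent replicate 2 the immediate early medians were 0.13 in perivascular macrophage-like and 0.10 in endothelial-like cells. Without naive replicate 1 the median was 0.089 for heat shock genes in perivascular macrophage-like cells and 0.011 for oxidative phosphorylation genes in GABAergic neuron-like cells. It was 0.080 for cytokine genes in microglia-like cells without dependent replicate 3 and -0.10 for homeostatic microglia genes in erythrocyte-like cells without naive replicate 2. The pairs of opposite sign were heat shock genes in microglia-like and oligodendrocyte-like cells (-0.056 and -0.027 without naive replicate 1) and ribosomal protein genes in GABAergic neuron-like (-0.066 without naive replicate 1), endothelial-like (-0.020 without naive replicate 2), astrocyte-like and oligodendrocyte precursor-like cells. In astrocyte-like cells their lowest median was -0.080, and it was below 0 without naive replicate 1 or 2 or dependent replicate 3. In oligodendrocyte precursor-like cells ribosomal protein genes had -0.030 and oxidative phosphorylation genes -0.040 without dependent replicate 3. Adjusted over the list alone, 9 members of the cytokine list passed, 12 of the heat shock list and 4 of the cell cycle list, against 0, 1 and 0 over all genes tested. Markers of other classes were called in 6 of 92 pairs, 5 of them down.

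Of 109372 gene and class pairs, 2 passed the edgeR test and 3038 had an unadjusted p under 0.05. The DESeq2 test called 34, of which 17 were in endothelial-like and 9 in astrocyte-like cells. With the replicate number as a block 7 were called, adding Dnajb1 in oligodendrocyte-like cells, Slc7a1, Axin2 and Emp2 in endothelial-like cells and Snhg11 in perivascular macrophage-like cells. With that block Dnajb1 had a log2 fold change of 1.17 (edgeR adjusted p = 0.00666), higher in 3 of 3 dependent libraries. The edgeR count was 1 without naive replicate 3, dependent replicate 1 or dependent replicate 3, and 4 without dependent replicate 2. The list count was 67 without naive replicate 3, 53 without dependent replicate 2 and 58 without dependent replicate 3. With the replicate number as a block it was 49.

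**Figure D2:**
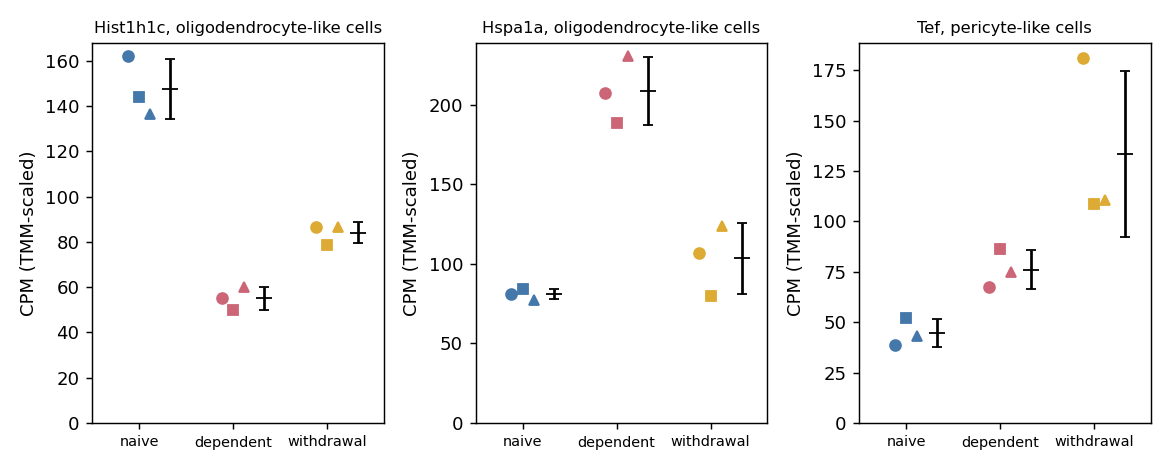
TMM-scaled CPM of the 3 called genes in each library, shaped by replicate number, with the group mean and SD (n = 3) beside them. Hist1h1c averaged 148 CPM in naive and 55.0 CPM in dependent libraries, Hspa1a 80.7 and 209 CPM, and Tef 44.6 CPM in naive and 134 CPM in withdrawal libraries.

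Withdrawal and naive libraries were compared to ask what differed 24 hours after morphine. In pericyte-like cells Tef, a clock-controlled transcription factor (ENSMUSG00000022389, chromosome 15, 81802421 to 81826863), rose from 44.6 ± 6.88 to 134 ± 41.3 CPM (SD, n = 3). Its log2 fold change was 1.44 ± 0.22 (SE; edgeR adjusted p = 0.0161), with 3 of 3 withdrawal libraries above every naive library. In simulated counts of this comparison with no gene changed, the same test called 2 of 7882 genes in pericyte-like cells. Withdrawal replicate 1 held 37 pericyte-like cells, against 91 to 242 in the naive libraries. Chosen after its values were seen, Tef had a positive value in 10 of 10 classes, with the groups apart in 5; the classes, pericyte-like cells among them, come from the same libraries, so this gives no measure of chance. Circadian clock genes rose by camera in 5 classes, with medians of 0.44 in pericyte-like and 0.32 in endothelial-like cells, and the calls in these 2 were the ones left without naive replicate 1 (pericyte-like median 0.27). With an estimated correlation 0 of the 70 list calls of this comparison remained, with an adjusted p = 0.758 at the lowest and an adjusted p = 0.943 at the highest with an estimated correlation. In pericyte-like cells Per3, a period gene of the clock, was at 15.01 and 52.0 CPM (log2 1.70 ± 0.37, edgeR adjusted p = 0.326) and Dbp, a clock output factor, at 97.6 and 181 CPM (log2 0.91 ± 0.19, edgeR adjusted p = 0.316), both higher in 3 of 3 withdrawal libraries. Heat shock and chaperone genes fell in 7 classes, with 16 of 16 members negative in astrocyte-like, microglia-like and oligodendrocyte precursor-like cells (medians -0.35, -0.30 and -0.21). Unfolded protein response genes fell in 7 classes, with the lowest median in choroid plexus-like cells (-0.38). Without naive replicate 2 each of these lists kept 2 of its 7 calls, and heat shock medians were -0.13 in microglia-like and -0.091 in oligodendrocyte precursor-like cells. In astrocyte-like cells Calr was at 384 and 280 CPM (log2 -0.46 ± 0.10, edgeR adjusted p = 0.907, DESeq2 adjusted p = 0.0147), lower in 3 of 3 withdrawal libraries.

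Cholesterol biosynthesis genes fell in oligodendrocyte-like cells, where 22 of 23 members were negative (median -0.39), and in GABAergic neuron-like cells (median -0.20), and rose in choroid plexus-like cells (median 0.15). The oligodendrocyte-like class drew 44.0% of its pooled withdrawal cells and 27.7% of its pooled naive cells from cluster 16, of lower UMI count. The rise came from withdrawal replicate 3, where cluster 16 held 4.38% of all kept cells. It held 0.567% and 0.899% of those in withdrawal replicates 1 and 2, and 0.677% to 1.39% in naive libraries. Myelin genes fell in 6 classes, with a median of -0.14 in oligodendrocyte-like cells, -0.45 in microglia-like, -0.42 in astrocyte-like and -1.31 in pericyte-like cells. Without withdrawal replicate 3 the median in oligodendrocyte-like cells was 0.028 and those in the other 3 were -0.70, -0.62 and -1.61, while in perivascular macrophage-like cells it was -0.38 with all libraries and 0.11 without withdrawal replicate 1. Without withdrawal replicate 1, 2 of the 6 myelin calls were left, with medians of -0.021 in microglia-like, -0.11 in astrocyte-like and -0.73 in pericyte-like cells, and without naive replicate 2 also 2. Oligodendrocyte markers as a list had medians of -1.47 in pericyte-like and -0.48 in microglia-like cells. Homeostatic microglia genes fell in astrocyte-like, erythrocyte-like, oligodendrocyte precursor-like and pericyte-like cells, where microglia markers had medians of -0.43, -0.69, -0.58 and -0.78. Of these 4 calls 0 were left without naive replicate 2, and without withdrawal replicate 1 the medians were -0.11, -0.056, -0.17 and -0.32. Astrocyte uptake genes fell in GABAergic neuron-like and microglia-like cells, where astrocyte markers had medians of -0.73 and -0.22. Marker lists of other classes were called in 22 of 92 pairs, 19 of them down. Nuclear oxidative phosphorylation genes fell in 9 classes (medians -0.25 to -0.08 where called) and ribosomal protein genes in 5, while the latter rose in GABAergic neuron-like cells (median 0.23). Without naive replicate 3 these falls were called in 2 and 1 classes. Immediate early genes rose in oligodendrocyte precursor-like and oligodendrocyte-like cells (medians 0.26 and 0.24). Interferon-stimulated genes fell in 3 classes, and cytokine and NF-kB target genes fell in astrocyte-like and microglia-like cells (medians -0.42 and -0.15). Reactive astrocyte genes fell in choroid plexus-like, microglia-like and oligodendrocyte precursor-like cells. Disease-associated microglia genes fell in GABAergic neuron-like and oligodendrocyte precursor-like cells, and MHC genes in microglia-like and oligodendrocyte precursor-like cells. Cell cycle and neuropeptide genes fell in oligodendrocyte precursor-like cells (medians -0.21 and -0.47; the latter -0.063 without naive replicate 3) and hypoxia genes in microglia-like cells. Cluster 9 held 27.8% of the naive and 14.99% of the withdrawal oligodendrocyte precursor-like cells (by library 13.4% to 40.6% and 9.60% to 23.7%). Blood-brain barrier genes rose in endothelial-like and fell in microglia-like cells (medians 0.07 and -0.17), where endothelial markers had a median of -0.22. Without withdrawal replicate 1 both calls ended (medians 0.043 and -0.0011). Glutamate receptor and GABA genes rose in choroid plexus-like cells (medians 0.38 and 0.39), where glutamatergic neuron markers had a median of 0.50. Of 250 list and class pairs 58 were called down and 12 up, each lost with an estimated correlation (lowest adjusted p = 0.758 with an estimated correlation), and fry called 0 (lowest adjusted p = 0.604). Of the 70 calls, 13 held in each of the 9 fits that left out 1 library, 59 had a median that moved by over 1.5 times and 7 one of the opposite sign in at least 1 of them, including the myelin medians above. Leaving out naive replicates 1 to 3 ended 13, 25 and 22 calls, withdrawal replicates 26, 15 and 15, and dependent replicates, which share the fit, 0, 2 and 1. Withdrawal replicate 1 was also the library with the lowest share of barcodes kept, and the part of its quality in these calls was not tested. None of the immediate early calls was left without naive replicate 1, of the MHC calls without withdrawal replicate 2, of the disease-associated microglia calls without withdrawal replicate 1, or of the cytokine calls without naive replicate 2 or withdrawal replicate 1. Without withdrawal replicate 1 the reactive astrocyte genes kept 1 of 3 calls and the astrocyte uptake genes 1 of 2. The hypoxia call ended without naive replicate 2 or withdrawal replicate 1 or 2, the cell cycle call without naive replicate 1, dependent replicate 2 or 3 or withdrawal replicate 3, the neuropeptide call without naive replicate 3 or withdrawal replicate 1, and the glutamate receptor call without withdrawal replicate 3. The cytokine median in astrocyte-like cells was -0.10 without withdrawal replicate 1, and medians in choroid plexus-like cells without withdrawal replicate 3 were 0.070 for cholesterol and 0.018 for GABA genes. Without withdrawal replicate 3 oxidative phosphorylation genes had 0.045 in choroid plexus-like cells, and without naive replicate 3 they had 0.010 and ribosomal protein genes 0.0061 in oligodendrocyte-like cells. Reactive astrocyte genes in choroid plexus-like cells had 0.017 without withdrawal replicate 1, and ribosomal protein genes in GABAergic neuron-like cells -0.077 without naive replicate 1. Adjusted over the list alone, 11 cholesterol, 10 heat shock, 9 clock and 8 myelin members passed, against 0, 0, 1 and 0 over all genes tested.

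Of 109372 pairs 1 passed the edgeR test and 3476 had an unadjusted p under 0.05. With the replicate number as a block 4 passed, 2 higher and 2 lower, and camera called 80 list pairs. DESeq2 called 12, of which 11 were lower, including Hist1h1c in oligodendrocyte-like cells (log2 -0.82 ± 0.12, edgeR adjusted p = 0.18, DESeq2 adjusted p = 0.000275), lower in 3 of 3 withdrawal libraries. The edgeR count was 0 without naive replicate 1, 2 or 3 or withdrawal replicate 1 or 2, and 2 without withdrawal replicate 3.

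Withdrawal and dependent libraries were compared to ask what differed once morphine had been stopped. Heat shock and chaperone genes fell by camera in 8 classes, with 16 of 16 members negative in microglia-like (median -0.55), endothelial-like (-0.40) and oligodendrocyte precursor-like cells (-0.35), and without dependent replicate 3 in 6 of the 8. Of the pooled microglia-like cells cluster 2 held 87.1% in dependent and 78.1% in withdrawal libraries, and cluster 18 held 5.33% and 10.6%. Before doublets were removed cluster 18 had 43, 79 and 108 cells in dependent and 28, 250 and 69 in withdrawal replicates 1 to 3. Its rise came mainly from withdrawal replicate 2. Of the pooled astrocyte-like cells cluster 1 held 50.8% and 42.8%. By replicate it held 43.1%, 45.8% and 58.3% in dependent and 51.8%, 45.5% and 29.3% in withdrawal libraries. Only withdrawal replicate 3 lay below every dependent library. The median UMI count of cluster 1 was 2002, below the lowest count of withdrawal replicate 3, 2155. With an estimated correlation 0 of the 59 list calls of this comparison remained, with an adjusted p = 0.962 at the lowest and an adjusted p = 0.983 at the highest with an estimated correlation. Hspa1a was at 313 CPM in dependent and 174 CPM in withdrawal libraries in microglia-like cells (log2 -0.85 ± 0.13, edgeR adjusted p = 0.229), and at 664 and 324 CPM in perivascular macrophage-like cells (log2 -1.04 ± 0.16, edgeR adjusted p = 0.138), lower in 3 of 3 withdrawal libraries in both. Cytokine and NF-kB target genes fell in 4 classes, with 15 of 15 negative in endothelial-like cells (median -1.07, and -0.54 without withdrawal replicate 1) and 21 of 21 in microglia-like cells (median -0.43). Endothelial Icam1 was at 160 and 76.7 CPM (log2 -1.04 ± 0.19, edgeR adjusted p = 0.279), lower in 3 of 3 withdrawal libraries. Immediate early genes fell in 4 classes (medians -0.28 to -0.24), of which 1 call was left without dependent replicate 2 or withdrawal replicate 1, with endothelial Ier3 at 639 and 359 CPM (log2 -0.83 ± 0.15, edgeR adjusted p = 0.279), lower in 3 of 3 withdrawal libraries.

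Nuclear oxidative phosphorylation genes fell in 10 of 10 classes (medians -0.29 to -0.15) and ribosomal protein genes in 9, with 51 of 51 negative in oligodendrocyte precursor-like cells (median -0.22, and -0.12 without dependent replicate 3). Without dependent replicate 3 the calls left were 2 of 10, in astrocyte-like and oligodendrocyte precursor-like cells, and 6 of 9. Unfolded protein response genes fell in 4 classes. Cholesterol biosynthesis genes fell in oligodendrocyte-like cells (median -0.35, 21 of 23 negative) and rose in choroid plexus-like and pericyte-like cells (medians 0.28 and 0.24). The rises held in 5 and 2 of 9 fits that left out 1 library, with medians of 0.11 without dependent replicate 3 and 0.060 without withdrawal replicate 1. Of the pooled oligodendrocyte-like cells cluster 16 held 26.2% in dependent and 44.0% in withdrawal libraries. Of all kept cells it held 0.591% to 1.39% in dependent libraries. In withdrawal replicates 1 to 3 it held 0.567%, 0.899% and 4.38%. Myelin genes fell in astrocyte-like, oligodendrocyte-like and pericyte-like cells (medians -0.39, -0.19 and -1.09), and in the last of these oligodendrocyte markers had a median of -0.99. Without withdrawal replicate 1 the myelin medians were -0.026 in astrocyte-like and -0.33 in pericyte-like cells, and without withdrawal replicate 3 the median was -0.034 in oligodendrocyte-like cells. Interferon-stimulated genes fell in microglia-like and perivascular macrophage-like cells and hypoxia genes in microglia-like and oligodendrocyte precursor-like cells. Glucocorticoid-responsive, antioxidant and reactive astrocyte genes fell in microglia-like cells (medians -0.056, -0.15 and -0.30). The glucocorticoid median was -0.27 without withdrawal replicate 3, and its call ended without dependent replicate 2 or withdrawal replicate 1. There Cdkn1a, a cell cycle inhibitor, was at 98.1 and 56.0 CPM (log2 -0.81 ± 0.11, edgeR adjusted p = 0.0696), lower in 3 of 3 withdrawal libraries. Homeostatic microglia genes fell in endothelial-like cells, mitochondrially encoded genes in choroid plexus-like cells, and cell cycle and disease-associated microglia genes in perivascular macrophage-like cells. Glutamate receptor genes rose in choroid plexus-like and perivascular macrophage-like cells (medians 0.34 and 0.63). Astrocyte uptake genes rose in pericyte-like cells (median 0.40), where astrocyte markers had a median of 0.43. Of 250 list and class pairs 54 were called down and 5 up, each lost with an estimated correlation (lowest adjusted p = 0.962 with an estimated correlation), and fry called 0 (lowest adjusted p = 0.852). Of the 59 calls, 25 held in each of the 9 fits that left out 1 library, 46 had a median that moved by over 1.5 times and 6 one of the opposite sign in at least 1 of them. Leaving out dependent replicates 1 to 3 ended 7, 15 and 16 calls, withdrawal replicates 18, 7 and 10, and naive replicates, which share the fit, 1, 1 and 1. Here too the quality of withdrawal replicate 1 was not tested as a source of these calls. Without withdrawal replicate 1 the antioxidant, homeostatic microglia, cell cycle, disease-associated microglia, mitochondrially encoded and astrocyte uptake calls ended, and without dependent replicate 1 the homeostatic microglia, disease-associated microglia, mitochondrially encoded and astrocyte uptake calls. The cell cycle call also ended without dependent replicate 2 or 3 or withdrawal replicate 3, the homeostatic microglia call without dependent replicate 2, and the disease-associated microglia call without withdrawal replicate 3. Without dependent replicate 2 interferon, hypoxia and myelin genes each kept 1 call. Without withdrawal replicate 3 the glutamate receptor medians were 0.12 in choroid plexus-like and 0.25 in perivascular macrophage-like cells, and without withdrawal replicate 1 the astrocyte uptake median in pericyte-like cells was 0.10. Oxidative phosphorylation genes in GABAergic neuron-like cells had a highest median of 0.093 and were above 0 without dependent replicate 3 or withdrawal replicate 1. In choroid plexus-like cells they had 0.047 without withdrawal replicate 3, mitochondrially encoded genes 0.046 without withdrawal replicate 1, and ribosomal protein genes 0.015 without dependent replicate 3 and 0.046 without withdrawal replicate 3. Homeostatic microglia genes in endothelial-like cells had 0.060 without withdrawal replicate 1, and ribosomal protein genes in microglia-like cells 0.0084 without dependent replicate 3. Adjusted over the list alone, 29 heat shock and 8 cytokine members passed, against 0 and 0 over all genes tested. Markers of other classes were called in 7 of 92 pairs.

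Of 109372 pairs 0 passed the edgeR test and 4980 had an unadjusted p under 0.05. With the replicate number as a block 9 passed, 9 of them lower, and camera called 69 list pairs. DESeq2 called 20, 19 of them lower, and 12 of the 20 were in endothelial-like cells. The edgeR count was 6 without dependent replicate 2, 3 without withdrawal replicate 3, 2 without withdrawal replicate 2, and 1 without naive replicate 2, dependent replicate 3 or withdrawal replicate 1.

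**Figure D3:**
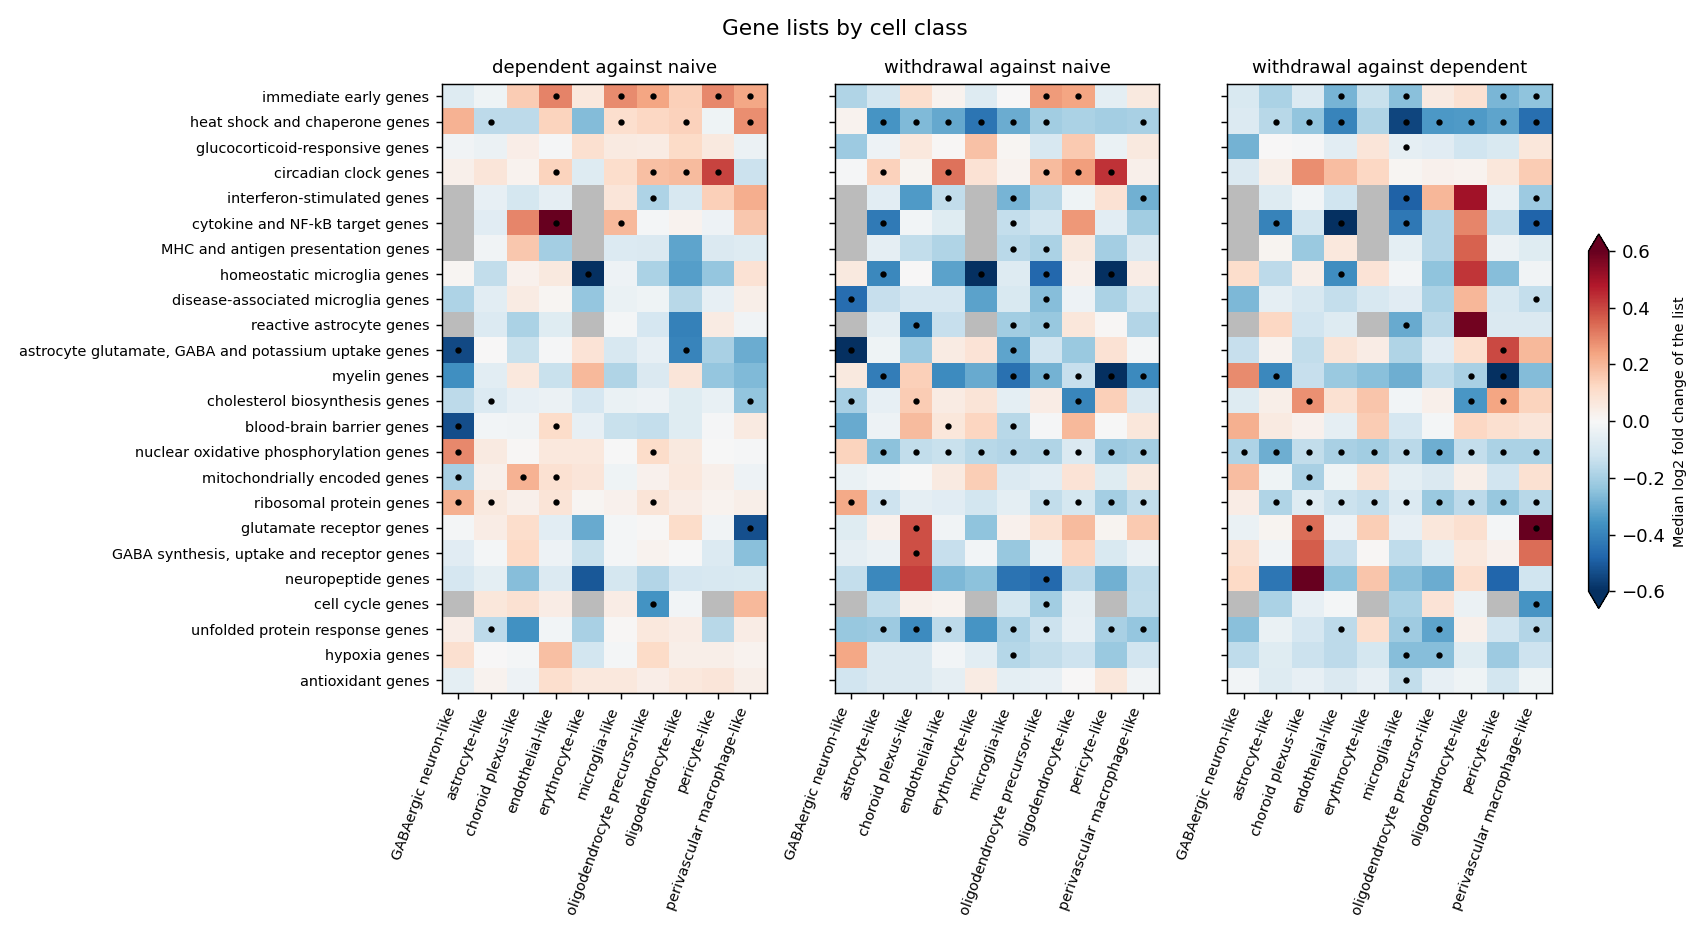
Median log2 fold change of each gene list in each class for the 3 comparisons, with colours stopping at -0.6 and 0.6, grey for pairs not tested and a dot for a camera call with the preset correlation. Oxidative phosphorylation genes carry a dot in 10 of 10 classes for withdrawal against dependent libraries, and 0 dots would remain in any panel with an estimated correlation.

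Tested together for any difference between the 3 groups, 2 of 109372 pairs passed the edgeR test, both in oligodendrocyte-like cells, 3470 had an unadjusted p under 0.05, and the DESeq2 likelihood ratio test called 66. The edgeR count was 1 without naive replicate 3 or dependent replicate 1, and 4 without withdrawal replicate 1 or 2. Oprm1, the mu opioid receptor, was tested in 1 class, GABAergic neuron-like cells, at 15.9, 15.9 and 19.9 CPM in naive, dependent and withdrawal libraries. Oprl1, the nociceptin receptor, was at 60.5, 61.8 and 59.7 CPM in oligodendrocyte precursor-like cells. Penk, the proenkephalin gene, was at 275, 742 and 238 CPM in GABAergic neuron-like cells, with a log2 fold change of 1.41 ± 1.02 for dependent against naive libraries. Cluster 48, led by Penk, held 9.19%, 13.7% and 5.54% of those cells in the 3 groups. For dependent against naive libraries Crh, the corticotropin-releasing hormone gene, had a log2 fold change of -1.05 ± 0.65 in the same cells. Pdyn, the prodynorphin gene, had 0.25 ± 0.50 in oligodendrocyte precursor-like cells, Fkbp5 -0.06 ± 0.48 in perivascular macrophage-like cells and Sgk1 -0.02 ± 0.11 in microglia-like cells, and none of these genes passed the main edgeR test in any comparison. Without a filter on low counts 2 tests of Penk passed, with the groups overlapping in both. The first was Penk in GABAergic neuron-like cells, dependent against naive libraries (log2 1.40, edgeR adjusted p = 0.0303, with 0.0303 to 1 over the alternatives), with 2 of 3 dependent libraries above the naive library of the same number. The second was Penk in GABAergic neuron-like cells, withdrawal against dependent libraries (log2 -1.70, edgeR adjusted p = 0.000622, with 0.000622 to 0.999993 over the alternatives), with 1 of 3 withdrawal libraries above the dependent library of the same number. Oprd1 and Oprk1 passed the count filter in 0 classes, so no difference in them was detectable at this depth. The opioid list could be tested in 1 class and was not called (camera adjusted p = 0.935, 0.666 and 0.61 for the 3 comparisons). The cAMP signalling and synaptic vesicle lists were called in 0 classes (lowest camera adjusted p = 0.17 and 0.0584), and the haemoglobin list had too few genes to test.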

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

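The thresholds behind the unnamed clusters below were chosen after the clusters had been seen, and no test was run on these values. Some clusters outside the named classes had their highest share in a withdrawal library, above the level in every naive library. Cluster 6 (2858 cells, median UMI count 2632), led by mt-Nd6 and Kif5a, held 25.1% of the cells of withdrawal replicate 3 and at most 0.561% of those of a naive library. It held 0.252% and 0.156% of the cells of withdrawal replicates 1 and 2, and 0% of its closest markers were raised. In withdrawal replicate 3 the lowest UMI count per barcode was 2155, against 500 to 601 in the other libraries. The part of barcode selection in the shares of that library was not tested. In the same library cluster 12, led by Meg3 and Snhg11, held 4.76% (at most 2.19% in a naive library), cluster 20, led by Mgp and Ccn3, 4.10% (at most 1.13%), and cluster 29, led by Meg3, 2.17% (at most 0.421%). Cluster 12 also held 2.98% of withdrawal replicate 1 and 2.21% of dependent replicate 3, and cluster 29 held 0.798% and 0.677% of these. Cluster 40, led by C1ql3 and C1ql2, held 1.43% of the cells of withdrawal replicate 1, 0.443% of those of withdrawal replicate 2 and at most 0.204% of those of a naive library.

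In some lists every library of a group moved one way in one class and the opposite way in another; these differences between classes were not tested. For dependent against naive libraries, blood-brain barrier genes had a mean log2 change of 0.16 in endothelial-like and -0.68 in GABAergic neuron-like cells, a difference of 0.85. Mitochondrially encoded genes had 0.13 and -0.18 in the same classes, a difference of 0.31. Neither of their camera calls there was kept without dependent replicate 1 or naive replicate 1. For withdrawal against dependent libraries, cholesterol biosynthesis genes had 0.24 in pericyte-like and -0.30 in oligodendrocyte-like cells, a difference of 0.54.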

How the results depend on the processing

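A common UMI floor, the floor together with the replicate block, and the removal of clusters of low UMI count were tests chosen only after the results were seen. Hist1h1c in oligodendrocyte-like cells was called in 22 of 22 settings (log2 -1.50 to -1.35), Hspa1a in 16 (1.29 to 1.44; adjusted p 1.07e-11 to 0.132) and Tef in pericyte-like cells for withdrawal against naive libraries in 15 (1.26 to 1.58; adjusted p 6.58e-06 to 0.232). DESeq2 size factors, kept doublets, the UMI floor alone and the removal of clusters of low UMI count gave 2, 1, 0 and 2 called gene and class pairs for dependent against naive, withdrawal against naive, withdrawal against dependent and any difference, as in the main setting. Against a fold of 1.2 the counts were 2, 1 and 0, and no such test was run for any difference. In the same order, the replicate block gave 7, 4, 9 and 6, the block with the UMI floor 13, 5, 11 and 13, the DESeq2 test 34, 12, 20 and 66, no filter on low counts 149, 125, 249 and 383, and adjustment over all classes together 1, 0, 0 and 1. Without genes open to free RNA 2 pairs were called for withdrawal against dependent libraries and 4 for any difference. Leiden resolution 0.5 gave 2, 1, 1 and 2. The stricter cell filter gave 3, 1, 0 and 1, and its call for withdrawal against naive libraries was Hist1h1c in oligodendrocyte-like cells, chosen after its values were seen, while Tef had 1.38 (edgeR adjusted p = 0.0719). Leaving out single libraries gave 1 to 4, 0 to 2, 0 to 6 and 1 to 4 pairs. The cause was not tested. By the limit of 0.1 the replicate numbers did not pair every withdrawal library with its naive (correlations 0.29, 0.12 and -0.03) or dependent one (0.20, 0.05 and 0.07). Not every one of these libraries correlated best with its own number. The labels describe batches with 1 library of each group, so a batch shared by number is not excluded for withdrawal libraries.

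List and class pairs called by camera were 35, 70 and 59 for the 3 pairwise comparisons with the preset correlation. An estimated correlation gave 0, 0 and 0 and fry gave 0, 0 and 0. The replicate block gave 49, 80 and 69, and leaving out single libraries 35 to 67, 51 to 97 and 59 to 85. Shares of cells had 0 called classes and library quality measures 0 called measures in every setting run.

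Among the named genes, 43 values under an alternative had the opposite sign, all of uncalled genes, and the cause was not tested. For dependent against naive libraries, Gpr34 in erythrocyte-like cells was 0.22 at Leiden resolution 0.5, and Fkbp5 in perivascular macrophage-like cells was 0.075 with the replicate block and 0.078 with the block and the UMI floor. For withdrawal against naive libraries, Penk in GABAergic neuron-like cells was 1.31 with the stricter cell filter. For withdrawal against dependent libraries, Slc1a2 and Slc1a3 in pericyte-like cells were -0.18 and -0.14 with doublets kept, Crh in GABAergic neuron-like cells -0.14 at Leiden resolution 0.5, and Fkbp5 in perivascular macrophage-like cells 0.044 with the stricter cell filter and 0.10 with doublets kept. Leaving out single libraries gave these ranges for dependent against naive libraries. In GABAergic neuron-like cells Oprm1 ranged from -0.37 to 0.34, Penk from -0.30 to 1.97 and Crh from -1.47 to 0.29. In oligodendrocyte precursor-like cells Oprl1 ranged from -0.036 to 0.10 and Pdyn from -0.045 to 0.26, in perivascular macrophage-like cells Fkbp5 from -0.54 to 0.38, and in microglia-like cells Sgk1 from -0.076 to 0.066. For withdrawal against naive libraries the ranges were -1.52 to 0.031 for Pnoc in oligodendrocyte precursor-like cells, -0.090 to 0.071 for Oprl1, -1.77 to 0.17 for Penk, -0.64 to 0.037 for Pdyn, -1.52 to 0.63 for Crh, -0.56 to 0.36 for Fkbp5 and -0.13 to 0.0024 for Sgk1. For withdrawal against dependent libraries they were -0.27 to 0.061 for Cst3 in endothelial-like cells, -0.12 to 0.038 for Oprl1, -3.19 to 0.059 for Penk, -0.46 to 0.77 for Crh, -0.33 to 0.32 for Fkbp5 and -0.12 to 0.026 for Sgk1. Of the other named-gene values under an alternative, 3864 kept their direction and side of the threshold, 77 passed it and 13 no longer did.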

Other observations

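The counts over other splits of 3 against 3 libraries, the UMI floor test of Hist1h1c, the tests on withdrawal replicate 3 and the tests on oxidative phosphorylation and ribosomal protein genes were chosen only after the results were seen, and so was the comparison of oligodendrocyte count shares between groups. The genes of this and the next paragraph were also chosen after their values were seen. H1f0, a linker histone of non-dividing cells, had a negative fold change for dependent against naive libraries in 10 of 10 classes, with the groups apart in 6. It was negative in 8 (apart in 3) for withdrawal against naive libraries and positive in 9 (apart in 5) for withdrawal against dependent libraries. Hist1h2bc, a histone H2B gene, was negative in 10 of 10 classes in each of these comparisons, with the groups apart in 2, 7 and 3. Pdia3, a disulfide isomerase, was negative in 10, 9 and 4 of 10 classes (apart in 7, 7 and 1) in the same order, and Pdia6, another one, in 9, 10 and 8 (apart in 7, 7 and 0). Dnajb1 was negative for withdrawal against dependent libraries in 9 of 9 classes (apart in 7), negative for withdrawal against naive libraries in 8 (apart in 0) and positive for dependent against naive libraries in 9 (apart in 4). Hspa8, a constitutive HSP70 chaperone, was negative in 10 of 10 classes for withdrawal against dependent (apart in 5) and against naive libraries (apart in 4), and in 5 of 10 for dependent against naive libraries (apart in 3). The classes come from the same libraries, so these counts give no measure of chance.

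In endothelial-like cells the DESeq2 test called Rsrp1, at 259 CPM in naive and 434 CPM in dependent libraries (log2 0.75 ± 0.11, DESeq2 adjusted p = 2.76e-06, edgeR adjusted p = 0.123), higher in 3 of 3 dependent libraries. It also called Tfrc, the transferrin receptor, at 539 and 876 CPM (log2 0.70 ± 0.15, DESeq2 adjusted p = 0.00221, edgeR adjusted p = 0.32), higher in 3 of 3. Emp2, a tetraspan membrane protein, was called at 126 and 77.6 CPM (log2 -0.70 ± 0.09, DESeq2 adjusted p = 9.23e-06, edgeR adjusted p = 0.0773), lower in 3 of 3. For withdrawal against dependent libraries DESeq2 called Csf1, a macrophage growth factor, at 57.2 and 26.3 CPM (log2 -1.10 ± 0.21, DESeq2 adjusted p = 0.00129, edgeR adjusted p = 0.279), lower in 3 of 3 withdrawal libraries.

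For the 3 pairwise comparisons there are 10 splits of 6 libraries, too few for a share under 0.05. For dependent against naive libraries the real split called 2 gene and class pairs and the highest other split 32, and 3 of the 10 splits called as many. The real split called 35 list and class pairs and the highest other 101, with 9 of 10 as many. Compared with the 3 other splits that also part every pair of replicate numbers, the real split called 2 pairs against 0 to 1, DESeq2 34 against 0 to 3, the edgeR test without a filter on low counts 149 against 59 to 232, and camera 35 list pairs against 26 to 58. Over all 9 other splits DESeq2 called 0 to 817 (4 as many) and the test without a filter 59 to 2199 (7 as many). For withdrawal against naive libraries the real split called 1 pair and the highest other 3 (6 of 10 as many), and 70 list pairs against a highest other of 129 (6 of 10). For withdrawal against dependent libraries these were 0 and 77 (10 of 10), and 59 and 115 (9 of 10). For withdrawal against naive libraries DESeq2 called 12 against 1 to 895 in the other splits (5 of 9 as many), and the test without a filter 125 against 225 to 2633, fewer than in every other split. For withdrawal against dependent libraries DESeq2 called 20 against 3 to 244 (5 of 9), and the test without a filter 249 against 329 to 2043, again fewer than in every other split. In the 3 other splits that part every number, edgeR called 0 and DESeq2 1 to 14 pairs for withdrawal against naive libraries. The test without a filter called 250 to 742 there, and camera 43 to 89 list pairs. For withdrawal against dependent libraries these were 0 to 3, 3 to 9, 329 to 685 and 46 to 86. With the real one such splits number 4, too few for a test. For any difference between the 3 groups, 48 of 100 groupings drawn from 280 called at least the real 2 pairs, so chance is not excluded. These groupings were drawn without regard to the replicate number. They do not show how often groupings with balanced numbers call as many. The highest grouping called 2498, and the one by replicate number called 1254, which points to a structure of the libraries by replicate number. With that number as a block 6 pairs were called.

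Hist1h1c was lower in dependent than in naive oligodendrocyte-like cells. The level of Hist1h1c in oligodendrocyte-like cells was 51.9% of that in choroid plexus-like cells, the highest class, which argues against RNA from other cells as the source of most of it. With cells held to a UMI floor of 2155 in all libraries its log2 fold change was -1.43, which argues against cells below that count as its source. The lowest UMI counts of the naive and dependent libraries were 500 to 601. This was therefore no test of an unequal floor between them. An effect of morphine stays open as a hypothesis, as do differences between the pools that follow neither.

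Myelin genes were lower in withdrawal than in naive libraries in some classes other than oligodendrocytes. By camera with the preset correlation they were called in astrocyte-like, microglia-like, oligodendrocyte precursor-like, pericyte-like and perivascular macrophage-like cells. They had medians above 0 in GABAergic neuron-like (0.058) and choroid plexus-like cells (0.15). Over the 9 libraries their level in microglia-like cells was correlated with the share of all counts lying in oligodendrocyte-like cells before adjustment and not after it (Pearson r = 0.697, permutation p = 0.0312, adjusted p = 0.0804 over 9 classes; Spearman rho = 0.883, permutation p = 0.00308; r = 0.730 without the 2 farthest libraries), while in pericyte-like cells r was -0.03. That relation met the condition set in advance for RNA from oligodendrocytes, but the share was 3.88% ± 1.49 in naive and 4.14% ± 0.876 in withdrawal libraries (SD, n = 3), so it was not lower in withdrawal; the withdrawal libraries had 3.32%, 4.05% and 5.06%, so this order depends on replicate 3 and lies within the spread. This second condition was added after r and the shares were seen. Of the 9 classes computed, only pericyte-like cells had r below 0. In the others r ran from 0.52 in perivascular macrophage-like to 0.77 in GABAergic neuron-like cells (permutation adjusted p 0.0804 to 0.167). Mbp, a member of the list, was at 129 CPM in microglia-like and 5357 CPM in oligodendrocyte-like cells. That is under the limit of 5% used for genes open to free RNA, so such RNA could supply it in microglia-like cells. RNA from oligodendrocytes as the explanation cannot be told apart from an effect of withdrawal. Without withdrawal replicate 3 the median log2 fold change in microglia-like cells was -0.70 (-0.45 with all libraries), which argues against that library as the cause, while without withdrawal replicate 1 it was -0.021 and 2 of the 6 myelin calls were left.

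Ribosomal protein and nuclear oxidative phosphorylation genes were lower in withdrawal than in dependent libraries by camera with the preset correlation. With an estimated correlation 0 of these calls remained (lowest camera adjusted p = 0.962), and the calls below are those with the preset one. With cells held to the same UMI floor, oxidative phosphorylation genes were still called in 10 of 10 classes, which argues against cells of low UMI count there. Ribosomal protein genes were still called in 8 of 9. These 8 classes were set apart by this outcome, so it is no test for them. In erythrocyte-like cells the ribosomal median moved from -0.14 to -0.11 and 0 calls were left. As that median shrank without reaching 0, cells of low UMI count cannot be told apart from an effect of withdrawal there. Without withdrawal replicate 3, oxidative phosphorylation genes were still called in 9 classes and ribosomal protein genes in 6, so these calls did not need that library. These classes were set apart by this same outcome after the values were seen. It is therefore no test of that library as a cause. In choroid plexus-like cells (medians 0.047 and 0.046) and, for ribosomal protein genes, erythrocyte-like (-0.14 to -0.052) and microglia-like cells (-0.082 to -0.053) 0 calls were left, with medians above 0 or smaller and fewer libraries, so that library cannot be told apart from an effect of withdrawal. Without dependent replicate 3 the calls left were 2 of 10 and 6 of 9, with oxidative phosphorylation medians of -0.14 to 0.027 and below 0 in 9 of 10 classes, which likewise leaves the part of that library open, and an effect of withdrawal stays untested.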
